A study of Danio rerio with 30 samples.

How the data were processed

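The data were RNA sequencing libraries of dissected zebrafish (Danio rerio) larval heads, eyes included, from fish carrying a mutation of znf804a. Per the labels' protocols, polyA RNA was extracted with a column kit and a DNase I step, and libraries were made with an in-house method based on SMART-Seq2, which copies whole polyadenylated transcripts into cDNA, followed by Nextera XT tagmentation. This chemistry does not mark the strand and adds no molecular identifiers, so PCR copies of a molecule were not told apart. Reads of a gene and of an overlapping antisense gene, and reads shared by near-identical genes, were likewise not separable from the values used here.

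For each of the 30 libraries the authors deposited whole-number counts per gene for 36351 genes. For each of the 24 libraries at 6 dpf (days post-fertilization) the authors also deposited RSEM expected counts and TPM (transcripts per M) for 111842 transcripts, per the file headers. The submitters' processing notes name STAR 2.7.3a, RSEM, DESeq2 and the genome build GRCz11. The gene annotation, the counting settings and the adapter or quality filters were not given in the sources used here. No reads were aligned or counted again.

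In every 6 dpf library, between 99.96% and 100% of the nonzero gene counts deposited by the authors were even numbers, against 47.66% to 48.54% in the 2 dpf libraries. Each fragment of a 6 dpf library therefore appears to be counted 2 times, and the number of independent fragments is nearer to the total divided by 2. Tests used the counts as deposited. A repeat with every 6 dpf count divided by 2 and rounded was added after the data were seen. Totals per library as deposited (M, mega) were 32.2 to 56 M at 6 dpf (16.1 to 28 M after division by 2) and 9.77 to 25.9 M at 2 dpf. The filter on low counts kept at least 99.97% of the counts of each 6 dpf library.

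The deposited tables identify genes by numbers with the prefix LL and do not pair them with gene symbols. The table of Ensembl gene IDs and symbols matched 0 of them. Through RefSeq transcript accessions listed in the isoform tables, a RefSeq gene table of the assembly GRCz12tu gave symbols for 75 of the 36351 genes, and 8 of these 75 were tested at 6 dpf. That table was used for names only. The level of znf804a, the calls on its chromosome and the 35 gene lists fixed before the data were examined are therefore not analysed here. Only 2 tested members of those lists had symbols, crygm2b of the lens list and hbbe1.2 of the erythroid list. The rule for named genes, which needed symbols, was replaced by the 2 genes with the smallest p that rose and the 2 that fell, in the genotype comparison averaged over light and dark and in the dark comparison of wild-type heads. Where a comparison called 5 or fewer genes, these were named after their values were seen.

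Samples were grouped by the titles in the labels into 6 groups of 4 libraries at 6 dpf and 2 groups of 3 at 2 dpf. File names of the 2 dpf libraries carry replicate numbers other than those of the titles, and the titles were used. Gene counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10, one mean per group without covariates, robust quasi-likelihood F-tests, and Benjamini-Hochberg adjustment with a threshold of 0.05 and no minimum fold. All 24 libraries at 6 dpf shared 1 fit of 25041 genes (common dispersion 0.0905), and the 6 libraries at 2 dpf had their own fit of 21982 genes (common dispersion 0.1129). "Called" below means an adjusted p under this threshold. The standard error of a log2 fold change was approximated as the fold change divided by the square root of F. Levels are given as CPM, counts per M after TMM scaling. Libraries of one age were compared in all pairs, 276 at 6 dpf and 15 at 2 dpf: their counts, divided by 2 at 6 dpf, differed by at least 14.5 and 19.8 times the sampling variance per gene, so no library was a copy of another of its age, and correlations of log2(CPM + 1) between replicates lay between 0.97 and 0.993.

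The test was tried on simulated counts with 200 genes changed in each of 5 draws. For hom vs wt, light, with 22874 genes, it recovered 18.8% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 80.6% of those changed 4-fold, and 4% of calls were false. For hom vs het, 2 dpf, with 21551 genes, it recovered 1.22%, 19.1% and 67% at these fold sizes. There 9.74% of calls were false, more than the threshold of 0.05 aims at. Simulated counts were drawn independently for each gene, without an effect of darkness or structure shared between genes. In the real data, other groupings of the dark hom and wt libraries called up to 539 genes. The recovered and false shares may therefore not hold for the real libraries.

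To see where called genes lay, genes were ranked by the median number of their assembled transcripts (the transcripts with the prefix TCONS), which 84.5% of the genes tested at 6 dpf had, and the order was divided into 25 windows of equal gene number. Within each window, the numbers were compared with those of reference transcripts of the same genes by rank correlation. These steps and the windows were chosen after the data were seen. Enrichment of calls in the last window was tested with Fisher's exact test, two-sided, against all tested genes with such a number. Shares of a gene's leading isoform were computed from TPM. Values per library were compared with exact two-sided permutation tests, for which the smallest p with 4 libraries against 4 is 0.0286.

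Alternatives chosen before the data were examined were RLE scaling factors, the DESeq2 1.42.0 Wald test, no low-count filter, a minimum count of 50, the replicate number as a block, a fit of only the groups compared, RSEM expected counts summed per gene and rounded to whole numbers, and leaving out each library. Alternatives added afterwards were counts divided by 2, these counts thinned to one depth, and 2 surrogate variables from sva 3.50.0. Other splits of the same libraries, at most 100 per comparison, were refitted for every comparison.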

Results

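Heads of zebrafish larvae mutant for znf804a, a zinc finger gene, were profiled by RNA sequencing together with their siblings. At 6 dpf, wild-type (wt), heterozygous (het) and homozygous mutant (hom) siblings of 1 clutch from heterozygous parents were compared under normal light cycling (light) or after constant darkness from 2 dpf (dark). Each of the 6 groups had 4 libraries of 4 pooled heads. At 2 dpf, hom and het siblings from a hom mother and a het father were compared, with 3 libraries of 3 pooled heads per group. Deposited totals ran from 32.2 to 56 M (mega) counts per library at 6 dpf and from 9.77 to 25.9 M at 2 dpf. At 6 dpf the counts were almost all even, so the number of fragments was nearer to 16.1 to 28 M per library. Between 26495 and 27868 genes had counts in a 6 dpf library. Genes are given by the identifiers of the deposited tables, which are not paired with symbols, and the level of znf804a in each genotype is not analysed here.

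The first principal component of the 24 libraries at 6 dpf held 16.9% of the variance and the second 12%. The second component parted the conditions without overlap: the 12 dark libraries lay between 7.9 and 56, and the 12 light libraries between -45.8 and -5.3. The first component did not follow a single factor. Of the dark hom libraries, replicates 2, 3 and 4 lay at -72.9, -57.5 and -104.8, beyond every other library, whereas replicate 1 lay at 47.9. The other groups spread from -40.1 to 39.4.

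**Figure D1:**
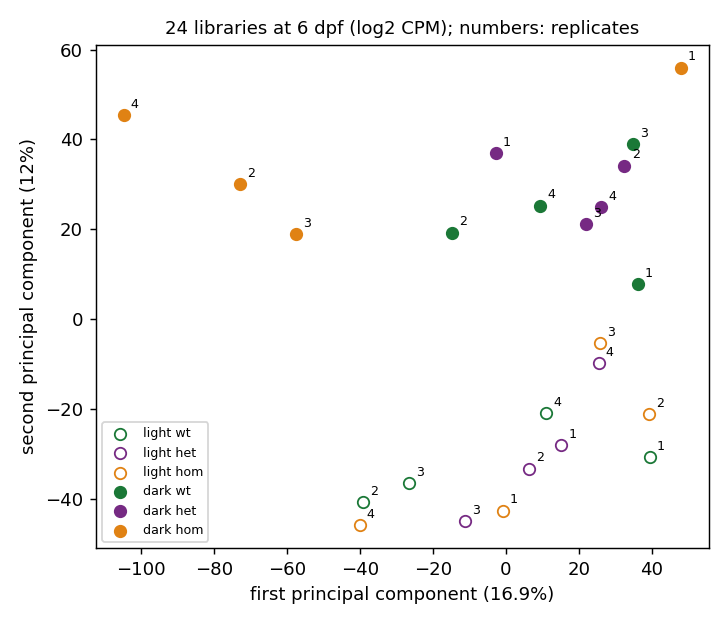
First 2 principal components of log2 CPM for the 24 libraries at 6 dpf; each point is a library, open for light and filled for dark, coloured by genotype and numbered by replicate. Dark libraries lie above light libraries on the second component (7.9 or more against -5.3 or less), and dark hom replicates 2 to 4 lie apart at -57.5 or less on the first.

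Gene expression differed between dark and light heads in each genotype. The gene with the smallest p in wt heads, LL0000007348, fell from 72.3 ± 10.1 CPM in light to 11 ± 0.9 CPM in dark (mean ± SD, n = 4 each), a log2 fold change of -2.72 ± 0.12 (SE; edgeR adjusted p = 6.79e-15). LL0000022817 fell from 1230 ± 218 to 45.4 ± 7.89 CPM (log2 fold change -4.76 ± 0.22, edgeR adjusted p = 8.38e-15). LL0000024818 rose from 11.5 ± 0.562 to 39.4 ± 3.37 CPM (log2 fold change 1.77 ± 0.13, edgeR adjusted p = 2.31e-10) and LL0000021508 from 12.8 ± 2.7 to 44.6 ± 7.32 CPM (log2 fold change 1.79 ± 0.16, edgeR adjusted p = 7.09e-09). These 4 genes were also called in het and in hom heads in the same direction. LL0000007348 changed by -2.56 ± 0.12 in het and -3.06 ± 0.12 in hom heads, and LL0000022817 by -4.41 ± 0.22 and -4.49 ± 0.22. LL0000024818 changed by 1.75 ± 0.13 in het and 1.81 ± 0.13 in hom heads, and LL0000021508 by 1.81 ± 0.16 and 1.99 ± 0.16. For each of the 4 genes, all 12 dark libraries lay on the same side of all 12 light libraries.

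Across the 25041 genes tested, darkness was followed by 779 calls in wt heads (332 higher in dark, 447 lower), 496 in het heads (124 higher, 372 lower) and 2327 in hom heads (892 higher, 1435 lower). Changes of more than 2-fold were mostly decreases: 187 lower against 82 higher in wt, 161 against 42 in het and 662 against 120 in hom heads. These 3 comparisons contrast different libraries within 1 shared fit. A set of 294 genes was called in all 3, each in the same direction, with 59 higher and 235 lower in dark. The median size of their log2 change was 1.08 in wt, 1.04 in het and 1.25 in hom heads. Between wt and hom, 131 genes were called higher in both, against 12 by chance for independent lists, and 324 lower in both, against 26 by chance (Fisher's exact p = 5.3e-102 and 5.88e-309). In opposite directions, 1 gene was called. The p-values of this overlap treat genes as independent, and all libraries came from 1 clutch. Both lists also rest on the same filter and the same estimate of spread per gene, so the overlap by chance may be larger than these values. Of the 779 wt calls, 731 (93.8%) had the same sign in hom heads, and of the 2327 hom calls, 1951 (83.8%) had the same sign in wt heads.

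Whether the larger number of calls in hom heads reflects a stronger response was not settled. The 496 genes called in het heads moved on average by 1.11 log2 units in hom and by 0.97 in wt heads in the direction seen in het. Their contrast compared het libraries only, but the filter, scaling and estimate of spread came from all 24 libraries. The difference of 0.14 did not pass (exact permutation p = 0.0992 over 4900 arrangements of genotype within condition, two-sided). By the signed mean log2 CPM of these genes, the dark hom libraries (-1.69 to -1.61) lay above the dark wt libraries (-1.89 to -1.76). In light, hom and wt libraries overlapped. Chosen by their response in het heads, these genes cannot show a response limited to hom heads. The hom count fell to 1235 without dark_hom replicate 4, to 1421 without light_hom replicate 1 and to 1400 without light_hom replicate 2. It was 599 with 2 surrogate variables. The wt count fell to 472 without dark_wt replicate 2 and to 425 without light_wt replicate 4, and it was 320 in a fit of the wt libraries alone, 1247 by DESeq2 and 1330 with 2 surrogate variables. The het count was 852 in a fit of the het libraries alone.

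**Figure D2:**
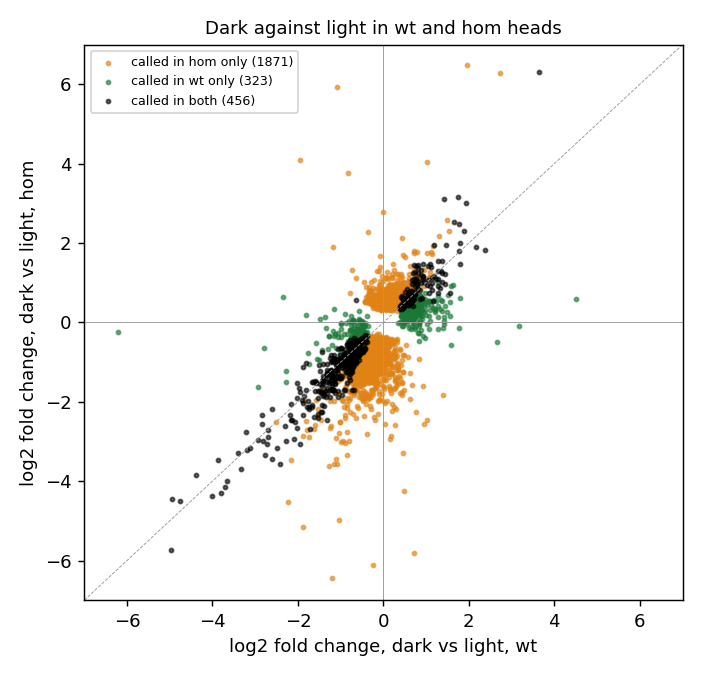
Log2 fold change of dark against light in wt heads (x axis) and hom heads (y axis) for genes called in either; each point is a gene, black where called in both, and the dashed line marks equal change. Of the genes called in both, 455 changed in the same direction and 1 in opposite directions.

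The comparison of hom with wt siblings, averaged over light and dark, called 89 of 25041 genes (54 higher in hom, 35 lower). The gene with the smallest p was LL0000019868, which fell by 1.03 on the log2 scale (SE 0.073, edgeR adjusted p = 1.03e-09). Its level was 83 ± 4.77 CPM in light wt and 38.8 ± 4.09 CPM in light hom heads, and 82.5 ± 10.9 and 42.2 ± 1.58 CPM in dark (mean ± SD, n = 4 each). LL0000005234, a gene of low level, fell from 3.98 ± 1 to 0.459 ± 0.149 CPM in light and from 3.38 ± 1.09 to 0.304 ± 0.0516 CPM in dark, a mean log2 change of -3.28 ± 0.27 (edgeR adjusted p = 1.47e-08). LL0000007282 rose from 71.3 ± 14.3 to 172 ± 9.22 CPM in light and from 84.2 ± 27.7 to 234 ± 43.1 CPM in dark, a mean log2 change of 1.37 ± 0.13 (edgeR adjusted p = 2.09e-07). LL0000012738 rose from 17.8 ± 1.7 to 52.2 ± 10.7 CPM in light and from 37.6 ± 13.6 to 87.2 ± 15.3 CPM in dark, by 1.38 ± 0.13 (edgeR adjusted p = 5.91e-07). In each condition, the 4 hom libraries lay on one side of the 4 wt libraries for each of these genes. The count of 89 was 214 by DESeq2, 187 without dark_hom replicate 1, and 48 both with 2 surrogate variables and in a fit without the het libraries.

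**Figure D3:**
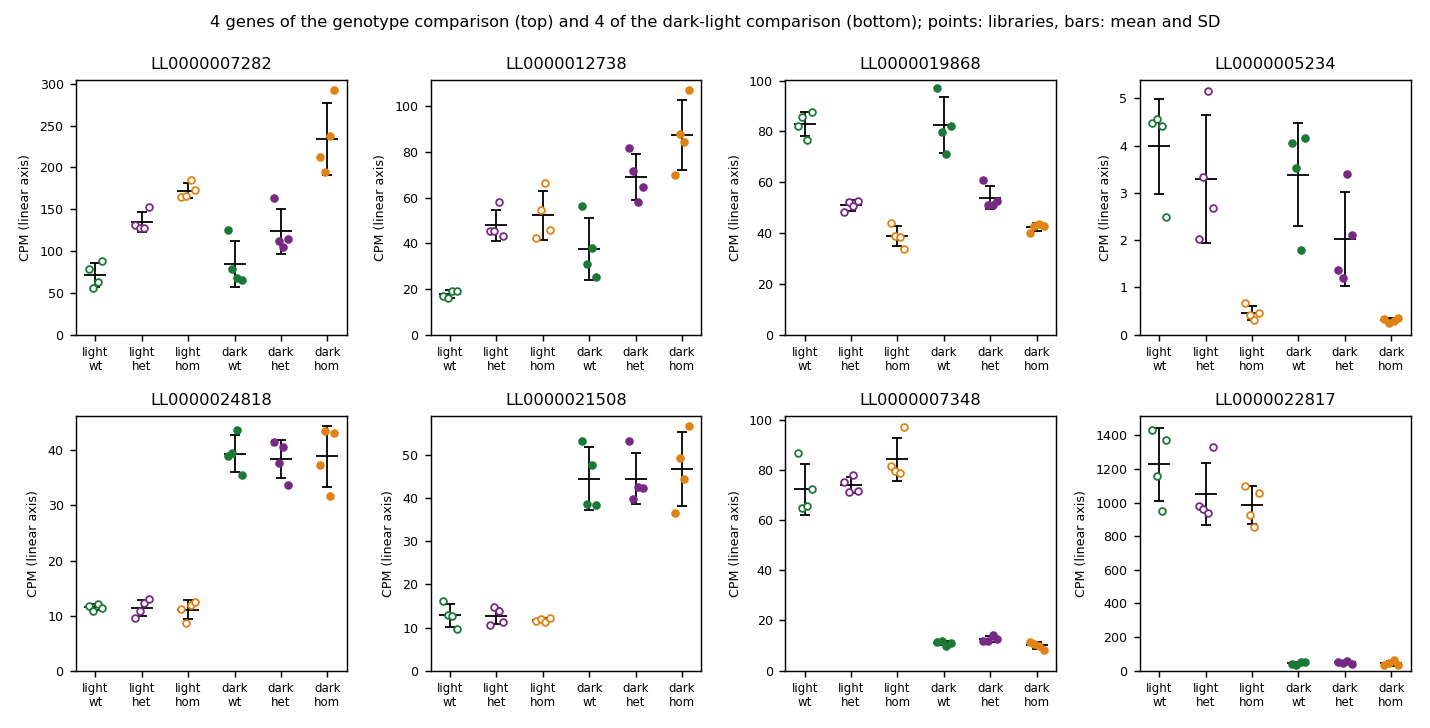
CPM per library at 6 dpf for the 4 genes named in the genotype comparison (top row) and the 4 named in the dark comparison (bottom row); open points are light, filled points dark, and bars show the mean and SD of 4 libraries. LL0000019868 lies between 33.9 and 43.9 in hom libraries and between 71 and 97.2 in wt libraries, with het libraries between 48.1 and 60.8.

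The genotype calls were unevenly placed along the numbering of the assembled transcripts. Of the 81 called genes with such a number, 42 lay in windows 24 and 25, which held 8% of the genes, with 22 higher and 20 lower in hom heads. No other window held more than 4. The last window alone held 18 of the 81 calls where 3.24 were expected (odds ratio 6.98, 95% interval 3.87 to 12, Fisher's exact p = 2.46e-09). In light, the last window held 10 of 36 calls where 1.44 were expected (Fisher's exact p = 9.84e-07), and in dark 23 of 271 where 10.8 were expected (Fisher's exact p = 0.00078). Hom vs het had 13 of 146 calls there in dark, where 5.84 were expected (Fisher's exact p = 0.00838), and 2 of 33 in light, where 1.32 were expected (Fisher's exact p = 0.383). The dark vs light comparisons had fewer calls in that window than expected: 19 of 706 in wt heads where 28.2 were expected (Fisher's exact p = 0.0779), 3 of 452 in het heads where 18.1 were expected (p = 2.54e-05) and 66 of 2075 in hom heads where 83 were expected (p = 0.0448). LL0000019868 and LL0000005234 belonged to window 24 and LL0000007282 and LL0000012738 to window 25. These p-values treat genes as independent, and the windows were set after the data were seen.

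**Figure D4:**
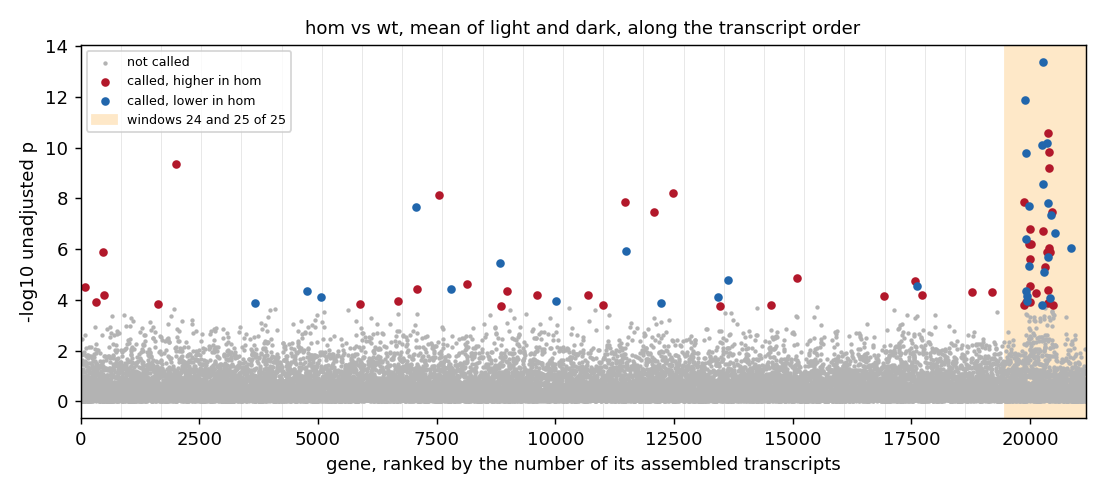
Unadjusted edgeR p (as -log10) of hom against wt, mean of light and dark, for each gene with an assembled transcript, ranked by transcript number; red genes were called higher in hom and blue genes lower, grey lines bound the windows, and the shaded part is windows 24 and 25. Of the 81 called genes shown, 42 lie in the shaded part.

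In light alone, hom and wt heads differed in 37 genes (25 higher in hom, 12 lower), and in dark alone in 306 (154 higher, 152 lower). The comparisons contrast different libraries within the shared fit. Both called 22 genes in the same direction (12 higher against 0.15 expected, 10 lower against 0.073 expected; Fisher's exact p = 9.18e-21 and 3.28e-21), and no gene was called in opposite directions. Here too the p-values treat genes as independent, and both lists rest on the same estimate of spread per gene. Of the 37 light calls, 35 (94.6%) had the same sign in dark. Of the 306 dark calls, 169 (55.2%) had the same sign in light. Outside the last window this was 152 of 283 (53.7%, 95% exact binomial interval 47.7% to 59.6%), with a median light change of 0.03 log2 units in the dark direction. These 283 include window 24, with 29 dark calls, and genes without a transcript number. Inside the last window, 17 of 23 had the same sign, with a median of 1 log2 unit.

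The number of dark calls depended on single libraries. It was 44 without dark_wt replicate 1, 103 without dark_wt replicate 2, 583 without dark_wt replicate 3, 998 without dark_wt replicate 4, 1041 without dark_hom replicate 1 and 58 without dark_hom replicate 4. In a fit of the 8 dark hom and wt libraries alone 13 genes were called, with 2 surrogate variables 9, and by DESeq2 1165. The light count was 19 without light_wt replicate 3, 24 without light_hom replicate 3 and 65 by DESeq2. Among the dark calls, 23 genes were abundant (mean log2 CPM above 8), of which 20 were higher in hom. Together these 23 made up 6.86% of all counts in dark hom and 4.37% in dark wt libraries. They were chosen as called in this comparison, so a difference in their share is partly built in. Whichever they were, the 50 most abundant genes of a library held 36.5% to 40.3% of its counts in dark hom. In dark wt libraries they held 34.8% to 35.7%.

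Of the lists fixed beforehand, 1 member each of the lens and erythroid lists could be named. The lens crystallin gene crygm2b was at 21.8 ± 3.01 CPM in dark hom and 11.7 ± 2.03 CPM in dark wt heads (mean ± SD, n = 4 each; log2 fold change 0.90 ± 0.25, edgeR adjusted p = 0.0651), and at 11.7 ± 1.94 and 15.5 ± 7.34 CPM in light. It rose in dark against light in hom heads (log2 fold change 0.89 ± 0.25, edgeR adjusted p = 0.0237). That call was lost without dark_hom replicate 2 (adjusted p = 0.0557) or 4 (0.0849) and without light_hom replicate 2 (0.0648) or 4 (0.0751), and the dark hom vs wt difference was called without dark_hom replicate 1 (0.048). The interaction of hom and dark was 1.3 ± 0.35 (edgeR adjusted p = 0.185). The globin gene hbbe1.2 was at 13.9 ± 9.31 CPM in dark hom and 23.4 ± 5.9 CPM in dark wt heads (log2 fold change -0.76 ± 0.6, edgeR adjusted p = 0.543) and passed in no comparison. No statement about lens or blood cells as a group follows from 1 gene of each, and crygm2b belongs to a family of similar genes that may share reads.

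Het siblings differed from wt in few genes. In light 3 genes were called: LL0000012738 rose by 1.42 ± 0.19 on the log2 scale (edgeR adjusted p = 0.00179), LL0000019868 fell to 51 ± 2.14 CPM (log2 fold change -0.70 ± 0.1, edgeR adjusted p = 0.00278), and LL0000006702 rose (edgeR adjusted p = 0.00502). LL0000006702 had no counts in the 4 light wt libraries and 0.574 ± 0.145 CPM in light het heads, at least 3.94-fold above a floor of 3 fragments per wt library (6 deposited counts, since each fragment appears to be counted 2 times). Light hom heads, at 0.98 ± 0.478 CPM, were at least 6.71-fold above it. In dark 2 genes were called, LL0000019868 (-0.61 ± 0.1) and LL0000007354 (-0.81 ± 0.14), both with edgeR adjusted p = 0.0289. LL0000006702 and LL0000007354 were named after their values were seen. Unadjusted p was under 0.05 for 2143 genes in light and 1744 in dark, and for 1219 in hom vs wt in light. Without any difference, a share of 0.05 of the genes tested would be expected in any comparison. DESeq2 called 15 and 19 genes. Neither dark gene kept its call without dark_het replicate 3 (edgeR adjusted p = 0.129 for both), where 2 genes were called. The dark count was 5 without dark_wt replicate 1, 1 without dark_het replicate 1 and 0 without dark_het replicate 2, dark_het replicate 4 or dark_wt replicate 4.

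Hom and het siblings differed in 40 genes in light (28 higher in hom, 12 lower) and in 165 in dark (79 higher, 86 lower). LL0000005234 was called in both, at -2.83 ± 0.37 in light and -2.71 ± 0.38 in dark (edgeR adjusted p = 0.000327 and 0.0027). Its het level was 3.3 ± 1.35 CPM in light (het vs wt log2 fold change -0.27 ± 0.33, edgeR adjusted p = 0.869) and 2.02 ± 1 CPM in dark (-0.75 ± 0.33, edgeR adjusted p = 0.674). LL0000007282 was called in dark (0.93 ± 0.18, edgeR adjusted p = 0.0149) and not in light (0.35 ± 0.18, edgeR adjusted p = 0.431). Both counts depended on single libraries. In light, the count was 19, 6, 7 and 93 without light_het replicates 1, 2, 3 and 4, and 9, 17 and 7 without light_hom replicates 1, 2 and 4. In dark, it was 344, 24, 58 and 11 without dark_het replicates 1, 2, 3 and 4, and 721, 80, 289 and 12 without dark_hom replicates 1, 2, 3 and 4. DESeq2 called 276 genes in light and 685 in dark, and with 2 surrogate variables 0 were called in dark.

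A test of the difference itself asked whether the hom effect changed with darkness. It called 2 of 25041 genes, both named after their values were seen. LL0000008839 was higher in hom than wt heads in light (15.5 ± 2.53 against 9.79 ± 1.13 CPM) and lower in dark (8.02 ± 0.553 against 11 ± 0.289 CPM), with an interaction of -1.12 ± 0.19. LL0000039288 was lower in hom heads in light (26.2 ± 2.21 against 32.9 ± 1.21 CPM) and higher in dark (41.2 ± 7.95 against 24.8 ± 3.96 CPM), with an interaction of 1.06 ± 0.18. Both had edgeR adjusted p = 0.045. The unadjusted p was under 0.05 for 2835 genes, and DESeq2 called 140. The edgeR count was 109 without dark_hom replicate 1, 42 without dark_wt replicate 4, 11 without light_hom replicate 1, 8 without dark_hom replicate 3, 6 without dark_wt replicate 2, 1 without light_hom replicate 3 or 4, and 0 without any of the others. For the het effect, edgeR and DESeq2 called 0 genes, with unadjusted p under 0.05 for 1065 and 1164 genes. For the hom effect, the edgeR count was also 0 with the replicate number as a block and with 2 surrogate variables. The same held in a fit of only the groups compared, with summed RSEM expected counts and with thinned counts. A difference of the hom effect between light and dark was thus not established for single genes.

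The comparison at 2 dpf had no wt group. There edgeR called 0 of 21982 genes between hom and het heads (smallest adjusted p = 0.809, unadjusted p under 0.05 for 502 genes). These 502 genes fall short of the share of 0.05 expected without any difference. DESeq2 called 4 (unadjusted p under 0.05 for 601 genes). The gene LL0000019868 was at 47.1 ± 4.07 CPM in hom and 55.3 ± 5.02 CPM in het heads (mean ± SD, n = 3 each; log2 fold change -0.23 ± 0.2, edgeR adjusted p = 1). LL0000005234, lower in 6 dpf hom heads, was at 2.78 ± 1.54 and 2.32 ± 0.821 CPM (log2 fold change 0.25 ± 0.53). The globin gene hbbe1.2 was at 46.5 ± 17.6 CPM in hom and 81.6 ± 11 CPM in het heads (log2 fold change -0.81 ± 0.25, edgeR adjusted p = 1). A simulated 2-fold change was found for 19.1% of genes in this comparison, so changes of that size could have been missed. The simulated counts held no structure shared between genes, so this share may not hold for the real libraries. The count was 2 without 2dpf_hom replicate 3 and 1 without 2dpf_het replicate 2. The 2 ages differ in parents, pool size and depth, and levels were not compared between them.

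**Figure D5:**
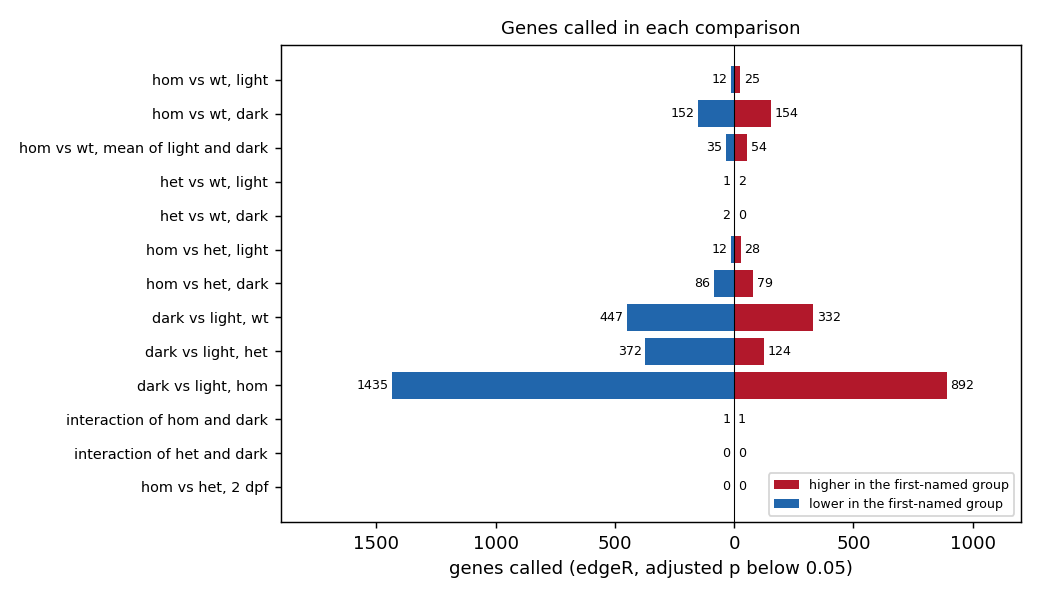
Number of genes called in each comparison (edgeR, adjusted p below 0.05), with genes higher in the first-named group to the right and lower to the left. An interaction counts as higher where the log2 difference of mutant from wt is more positive in dark than in light. The counts run from 0 for hom vs het at 2 dpf to 2327 for dark vs light in hom heads.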

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

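The tests in this part follow rules set before the data were examined, except the fits with counts divided by 2, thinned counts or surrogate variables, which were chosen after the result was seen. In the test of whether the hom effect differs between light and dark, LL0000008839 (interaction -1.12 on the log2 scale) and LL0000039288 (1.06) were called with edgeR adjusted p = 0.045. These calls were lost in 14 and 16 of 26 other fits each, with adjusted p up to 0.295 and 0.7, and 5 of 100 splits of the libraries called as many genes (2, highest other 231), so chance was not excluded. Of 96 groups of 4 values checked for a library far from the other 3, 7 had one, and chance gives about 1 in 20. LL0000007282 had a dark het library at 163 CPM where the others lay between 105 and 114, and a light het library at 153 CPM where the others lay between 127 and 131. LL0000012738 had a light het library at 57.9 CPM (others 43 to 45.4), LL0000005234 a light wt library at 2.48 CPM (others 4.42 to 4.56) and LL0000007348 a light hom library at 97.1 CPM (others 78.9 to 81.4). LL0000022817 had a light het library at 1330 CPM (others 937 to 981), and hbbe1.2 a light wt library at 25.4 CPM (others 8.15 to 10.2).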

How the results depend on the processing

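The alternatives were chosen before the data were examined, except the counts divided by 2, the thinned counts, the surrogate variables and the repeat without the last window. Direction held for each of the 33 single-gene results in all 641 values from alternative fits. Of these values, 578 kept their side of the threshold, 60 lost the call and 3 gained it. The fits reuse the same libraries, and most of the genes were chosen for a small p in them. A held direction is therefore not independent evidence. LL0000005234 and LL0000007282 stayed called in every hom vs wt fit, LL0000019868 likewise, and the 4 genes named for darkness in every dark vs light fit. The losses were in LL0000012738 in dark (2), the het calls of LL0000006702 (1), LL0000007354 (10) and LL0000019868 in dark (11), crygm2b (6), and the interactions of LL0000008839 (14) and LL0000039288 (16). The causes were not tested, except where fewer libraries, genes or counts entered a fit. RLE factors moved no count by over 1.5 times and no median over all genes by more than 0.1.

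DESeq2 called more genes: 65 (hom vs wt, light), 1165 (dark) and 214 (mean), 15 (het vs wt, light) and 19 (dark), 276 (hom vs het, light) and 685 (dark), 1247 (dark vs light, wt), 140 (interaction of hom and dark) and 4 (2 dpf). All 37 light and 89 averaged edgeR calls were among them, and 300 of the 306 dark calls. A fit of only the groups compared called 13 (hom vs wt, dark), 48 (mean), 6 (het vs wt, light), 0 (het vs wt, dark), 94 (hom vs het, light), 50 (dark), 320 (dark vs light, wt), 852 (het), 1550 (hom) and 0 (interaction of hom and dark). With 2 surrogate variables the counts were 9 (hom vs wt, dark), 48 (mean), 1 (het vs wt, dark), 0 (hom vs het, dark), 1330 (dark vs light, wt), 599 (hom) and 0 (interaction of hom and dark). Without a filter het vs wt gave 5 in light and 1 in dark, and with a minimum count of 50 it gave 0 in dark. Summed expected counts gave 0 (het vs wt, dark), 102 (hom vs het, dark) and 0 (interaction of hom and dark). Counts divided by 2 gave 7 (het vs wt, light), and thinned counts 6 (het vs wt, light), 0 (dark) and 0 (interaction of hom and dark). At an adjusted p below 0.01, hom vs wt in light and dark shared 11 calls and dark vs light in wt and hom shared 255. Without the last window the former was 13. DESeq2 placed 16 light and 28 averaged hom vs wt calls in the last window, a count whose repeats were added after the data were seen.

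The replicate numbers were not taken to pair the libraries, since not every same-numbered pair correlated by over 0.1 (12 of 60 did): deviations of same-numbered libraries at 6 dpf correlated by 0.01 on average (-0.174 to 0.35; permutation p = 0.252, one-sided, 10000 shuffles of the numbers within groups). Of 24 libraries, 11 correlated best with one of their own number where shuffles gave 6.02 on average (permutation p = 0.0543, one-sided), so some sharing by number stays open. These shuffles were added after the data were seen. At 2 dpf the 3 pairs had correlations between -0.392 and -0.114. With the number as a block, edgeR called 886 (hom vs wt, dark), 7 (het vs wt, light), 4 (het vs wt, dark), 88 (hom vs het, light), 422 (hom vs het, dark) and 0 (interaction of hom and dark). The other counts stayed within 1.5 times.

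Leaving out 1 library gave 19 to 29 calls for hom vs wt in light, 44 to 1041 in dark and 63 to 187 for the mean. It gave 3 to 4 for het vs wt in light and 0 to 5 in dark, 6 to 93 for hom vs het in light and 11 to 721 in dark. It gave 425 to 1051 for dark vs light in wt, 349 to 427 in het and 1235 to 2830 in hom heads, 0 to 109 for the interaction of hom and dark, 0 to 0 for that of het and dark, and 0 to 2 at 2 dpf. The planned tests of gene lists, of znf804a and of its chromosome, with their alternatives, were not run because identifiers were not paired with symbols. At 2 dpf depth and 3 libraries per group limit what small changes can be seen.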

Other observations

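The leading isoform of LL0000007282 by TPM made up a larger share of the gene in hom than in wt heads, 53.2% ± 1.7 against 34.9% ± 1.7 in light and 62.9% ± 4 against 36.5% ± 13 in dark (mean ± SD, n = 4 each; exact permutation p = 0.0286 for both, the smallest possible, and 0.0763 after adjustment over 8 tests on the 4 genotype genes). The gene's TPM was 75.3 in hom and 35.8 in wt heads in light, and 104 and 43.2 in dark. For LL0000005234, its leading isoform had a share of 0% in dark hom and 40.4% ± 23 in dark wt heads (exact permutation p = 0.0286, adjusted 0.0763), at a TPM of 0.162 and 3.67 for the gene. In light these shares were 14.3% ± 17 and 39.9% ± 27 (exact permutation p = 0.229, adjusted 0.294). For the leading isoforms of LL0000012738 and LL0000019868 the adjusted p ran from 0.228 to 0.629. These tests were chosen after the gene-level result was seen.

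The next paragraphs weigh 2 patterns that were noticed in the data, and the tests on the fullest window of each split, on transcript numbering, on het heads, on 2 dpf signs and with surrogate variables were chosen after the result they measure had been seen in full or in part. The first pattern is the gathering of hom vs wt calls at the end of the transcript order. In the averaged comparison, 1 of 100 splits, the real one, had as many calls in its own fullest window (24, highest other 13). In dark alone, 2 of 35 splits did (29, highest other 31). Most other splits called 0 genes and could not fill a window, so these shares cannot exclude chance for the gathering itself. In the averaged comparison, the other splits with 89 or more calls had 99, 140 and 166. Their fullest windows held 8, 10 and 13 of these. A numbering without any order shared with the reference transcripts is argued against inside the last window by a rank correlation of 0.959 between both kinds of number over 24 genes; over all 1366 genes with both it was -0.131, and in the other windows it ran from -0.436 to 1, so the order of the windows among themselves is not established. A candidate explanation is a difference that follows the number of mutant chromosomes. For the 23 last-window genes called in dark, the median light change was 1 log2 unit in hom and 0.26 in het heads (quartiles -0.11 and 0.82 over genes). The ratio of 0.26 lies near the lower edge of the range of 0.25 to 0.75 set for it. In light, 15 of the 23 had the dark sign in het heads, and 14 had a het change between 0 and the hom change. The other genes did not follow such grading. The mean of the 23 genes per library, signed as in dark, was above wt by 0.92 in hom and 0.40 in het heads. It differed by 0.52 between hom and het (exact permutation p = 0.0286 each, n = 4). At 2 dpf, where the parents differed, 15 last-window genes called in hom vs wt averaged over light and dark were tested. Of these, 12 (80%, exact binomial interval 51.9% to 95.7%) had the 6 dpf sign. Among averaged calls elsewhere, 41 of 66 did (62.1%, interval 49.3% to 73.8%), and these intervals overlap. Elsewhere here includes window 24, with 24 averaged calls at 6 dpf, and genes without a transcript number. The intervals treat genes as independent, though all were measured in the same 6 libraries. Poorer mapping of reads from the mutant chromosome is argued against for the 22 of 42 calls in windows 24 and 25 that were higher in hom; whether the mutation, variants inherited with it, or poorer mapping of either parental chromosome gene by gene causes the difference stays open, and the position of znf804a in this order was not used here.

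The second pattern is the larger number of hom vs wt calls in dark (306) than in light (37). A difference in depth is argued against, since 332 genes were called in dark and 34 in light after all libraries were thinned to one depth. A difference between libraries that also runs within groups is a candidate explanation: with 2 surrogate variables 9 genes were called in dark and 42 in light, and calls ended through both a smaller median change of the 306 genes (0.82 to 0.54) and a wider median SE (0.18 to 0.21), while for the 52 of them in windows 24 and 25 the change went from 0.93 to 0.87, the SE from 0.17 to 0.22, and 6 stayed called, against 2 of the 254 others. Surrogate variables can also take up a genotype effect, and a stronger effect of the mutation in dark cannot be told apart, since its test (152 genes, 0.73 log2 units in dark and -0.01 in light, exact permutation p = 0.0135) used genes chosen with the dark hom libraries. A larger share of lens in the dark hom pools also stays open, since the 154 genes called higher had a median correlation of 0.033 with crygm2b within the other 5 groups, which 127 of 1000 random lists reached.

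The same libraries were also split in every other way, or in 100 drawn ways where there were more. For hom vs wt in light, 1 of 35 splits, the real one, called as many genes (37, highest other 10). The same held for hom vs het in light (1 of 35, 40 and highest other 0), though leaving out 1 library gave 6 to 93 calls. The real split was also alone for dark vs light in wt (1 of 35, 779 and highest other 115), het (1 of 35, 496 and highest other 0) and hom heads (1 of 35, 2327 and highest other 254). For hom vs wt averaged over light and dark, 4 of 100 drawn splits called as many genes (89, highest other 166). This share is under 0.05 by a narrow margin, so the evidence against chance there is weak. For het vs wt the share was 1 of 35 in light (3, highest other 1) and in dark (2, highest other 1). These margins are of few genes, and leaving out 1 library gave 0 to 5 calls in dark. The evidence against chance for het vs wt is therefore weak too. A share of 1 of 35 was the smallest possible, and shares were not adjusted over the 13 comparisons. Such a share argues against chance but does not alone exclude it. The share was 0.05 or more for hom vs wt in dark (3 of 35, 306 and highest other 539), hom vs het in dark (3 of 35, 165 and highest other 353) and the interaction of hom and dark (5 of 100, 2 and highest other 231), so chance stays open there. For the interaction of het and dark the real split called 0 genes (highest other 1). All 100 splits reach that count, so the share decides nothing. The highest counts of other splits, 539 and 353 among dark libraries, 166 for the average and 231 for the interaction of hom and dark, point to a structure of the libraries other than genotype. At 2 dpf, 10 splits are too few for a share under 0.05 (0 genes called, highest other 291).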
